A study of Mus musculus with 91 samples.

How the data were processed

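Chromatin accessibility was measured by ATAC-seq in 91 libraries of sorted mouse T cells, in 12 groups formed by 3 states of gut colonization and 4 cell types. Cells were sorted by flow cytometry and their nuclei were treated with a transposase, per the labels' protocols. Each library was assigned to its group from its sample title and labels, and each library carries a number from 1 to 8. The authors deposited 1 list of peak intervals per library, with chromosome, start and end and no other column, so there is no score, height, fold or read count for a peak. The positions are on the mm10 genome, and Bowtie2 and SAMtools were used, per the submitters' processing notes, which give no versions. The peak caller, its threshold and any shift of reads to the transposase cutting site are not given in the sources used here. The lists differ between libraries and are treated as called per library. Sequencing depth is unknown, so no interval for counting error can be given, and the number of peaks in a list, from 3778 to 49510, was used as a stand-in for how much each library could detect. No pair of lists was identical (0 identical lists, highest bound on the Jaccard index of a pair 0.8405).

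Intervals that overlapped or touched were merged over all 91 lists, which held 2356027 peaks, into 73932 regions, and bedtools 2.31.1 gave 73932 as well. The 57775 regions with a peak in at least 5 libraries were used, of median width 640 bp, and 1824 of them were present in all libraries. A region counted as present (1) in a library with a peak over at least 1 bp of it and as absent (0) otherwise. Coordinates are given 1-based on mm10. Genes came from the annotation of GRCm38 patch 6, the assembly behind mm10, with 22301 genes used, 21887 of them protein coding. The table gives gene spans without strand, so a gene end stands in for the transcription start site planned at first, and both ends of a gene count. Regions within 1 kb of either end of a gene (21.9%) were called gene end, others overlapping a gene (44.9%) inside gene, and the rest (33.2%) between genes. A region was assigned to the gene with the nearest span, and for gene lists only within 50 kb, which covered 91.3% of regions. The nearest gene need not be the one a region regulates.

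Regions were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the presence matrix, with log10 peak number as a covariate, cell type comparisons also with colonization state, two-sided, with Benjamini-Hochberg adjustment over the regions tested. Regions present in at least 4 and absent in at least 4 of the libraries compared were tested, and an adjusted p under 0.05 was called. Differences are adjusted differences in the share of libraries with a peak, and in some comparisons limma assigned all regions the same variance, so that a standard error recurs. The comparisons were IELs with peripheral T cells, the IEL types with each other, CD4 with CD8 T cells, each pair of states within each cell type, and the difference between germ-free and conventionally raised mice in IELs against that in peripheral T cells. Peak number and the share of peaks at gene ends were compared with exact two-sided permutation tests between states and with 100000 resamples between IELs and peripheral T cells (scipy 1.17.1), adjusted by Benjamini-Hochberg over 12 comparisons. The similarity of libraries was tested with adonis2 of vegan 2.7.1 on Jaccard distances (permutation p, marginal terms). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

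There were 21 gene lists with 323 genes, 320 of them in the annotation, covering T cell programs, signalling, metabolism, housekeeping and markers of other cell types the sort could hold. They were tested with camera in limma (preset correlation 0.01, and again with an estimated correlation) where at least 5 regions were tested, adjusted over the lists of a comparison. Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule, in each cell type comparison up to 4 members of each list with the most called regions could be named, with the 5 regions of largest difference in each direction. In each colonization comparison up to 10 called regions in each direction could be named, by adjusted p. Where no region was called, only list members under an unadjusted p of 0.001 could be named. Label check genes were always reported. Genes of regions that differed between states with the cell types pooled (Mid1, Gm52481, Egf, Inpp4b, Fli1, Satb1) were named after their values were seen.

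The region test was checked on simulated presence data built from the libraries' own region frequencies and peak numbers. With no effect, the median number of calls was 0 in the comparisons between IEL types, CD4 with CD8 T cells and states, with a highest count of 1, but 131.5 with a highest count of 226 for the comparison of colonization differences (10 simulations each). Regions were drawn independently given the library, so these counts do not cover false calls from correlated regions. Random splits of the real libraries called up to 1275 regions (conventionally raised against conventionalized CD4 T cells, median 0). Of 100 regions shifted by 4 on the logit scale, 49 were recovered for TCRαβ+ against TCRγδ+ IELs (38510 regions run), 61 for CD4 against CD8 T cells (37427 regions). The number was 3 for germ-free against conventionally raised TCRαβ+ IELs (24213 regions), 1 for the same states in TCRγδ+ IELs (26218 regions) and 0 in each of the other comparisons between states. At a shift of 2 the numbers were 1, 3, 1 and 0 in the same order.

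The alternatives fixed beforehand were at least 50% of a region covered, the longest 50% of each list in place of a stricter score, at least 10 libraries per region, windows of 500 bp, no peak number term, Fisher's exact test and no libraries under 10000 peaks. Others were the longest 8000 peaks of each list, the library number as a block, gene distances of 10 kb and 100 kb, a gene end window of 2.5 kb, and covered length in place of peak number. Other peak number slopes, a term for library numbers 1 to 4 against 5 to 8 and the omission of single libraries were added after the data were seen. Motifs in the called regions were planned and not run, since no genome sequence was used here.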

Results

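Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in sorted mouse T cells. The 91 libraries came from C57BL/6 mice in 3 states of gut colonization. Germ-free mice carry no microbes, conventionally raised mice acquire theirs from birth, and conventionalized mice were given the gut microbiota of a donor. From the intestine, TCRαβ+ and TCRγδ+ intraepithelial lymphocytes (IELs) were taken, which are T cells lodged among the cells that line the gut, and from the periphery CD4 and CD8 T cells. There were 8 libraries in each germ-free group and 8 in each conventionally raised group, except 7 of conventionally raised CD8 T cells. The conventionalized groups held 7 TCRαβ+ IEL, 6 TCRγδ+ IEL, 8 CD4 and 7 CD8 libraries. Each library is a list of peak positions on the mm10 genome with no score or read count, so sequencing depth is unknown and a region is either present in a library or not. Nothing in the labels says that libraries came from separate mice, so p-values measure the spread between libraries, part of which may be technical.

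The number of peaks differed widely within every group. It ran from 3778 to 49510 with a median of 25547, and 6 libraries held fewer than 10000. TCRαβ+ IELs had 33370 ± 14477 peaks (SD, n = 8) in germ-free, 23585 ± 8067 (SD, n = 8) in conventionally raised and 23406 ± 12689 (SD, n = 7) in conventionalized mice. TCRγδ+ IELs had 33341 ± 14632 (SD, n = 8), 20674 ± 8901 (SD, n = 8) and 21505 ± 12090 (SD, n = 6) in the same order. CD4 T cells had 28615 ± 9729 (SD, n = 8), 20250 ± 9426 (SD, n = 8) and 26071 ± 13480 (SD, n = 8). CD8 T cells had 26996 ± 10134 (SD, n = 8), 19528 ± 11923 (SD, n = 7) and 31892 ± 10851 (SD, n = 7). None of the 12 comparisons between states passed an exact two-sided permutation test of mean log10 peak number. The largest difference was between conventionally raised and conventionalized CD8 T cells, at -0.31 on the log10 scale (exact permutation p = 0.0973, Benjamini-Hochberg p = 0.354). The smallest exact permutation p was 0.0842 (germ-free against conventionally raised CD4 T cells, Benjamini-Hochberg p = 0.354).

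**Figure D1:**
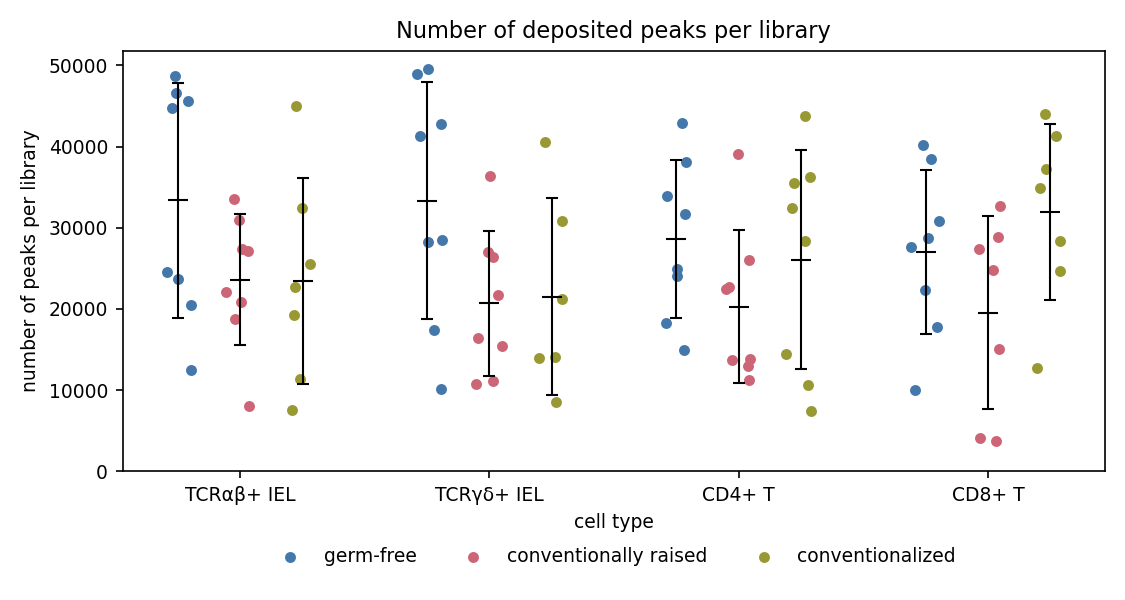
Number of peaks per library (vertical axis) by cell type and colonization state, with each point a library and bars the mean ± SD. The 12 groups overlap, from 3778 peaks in a conventionally raised CD8 library to 49510 in a germ-free TCRγδ+ IEL library.

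Longer peak lists held a smaller share of peaks near genes. The share of peaks within 1 kb of either end of a protein-coding gene was 40.4% ± 11.9 (SD, n = 45) in IELs and 36.6% ± 9.31 (SD, n = 46) in peripheral T cells (two-sided permutation p = 0.0937). Among the 12 comparisons between states it passed in none, and the smallest exact permutation p was 0.0856, for CD4 T cells of germ-free (33.6% ± 5.77, SD, n = 8) against conventionally raised mice (39.6% ± 7.16, SD, n = 8; Benjamini-Hochberg p = 0.437). Across libraries of a cell type this share fell with log10 peak number. Pearson's r was -0.993 in TCRαβ+ IELs (n = 23), -0.997 in TCRγδ+ IELs (n = 22), -0.995 in CD4 T cells (n = 24) and -0.992 in CD8 T cells (n = 22). Spearman's rho was -0.991, -0.998, -0.992 and -0.989 in the same order, and each permutation p was 1e-04, the smallest these permutations can give. Without the 2 libraries farthest from the median, r was -0.988, -0.997, -0.993 and -0.975.

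Cell type set the libraries apart far more than colonization did. Over the 57775 consensus regions, log10 peak number accounted for 31.5% of the variation in Jaccard distance and cell type for 23.1% (adonis2, marginal terms, each permutation p = 1e-04, the smallest these permutations can give). Colonization state accounted for 1.52% (permutation p = 0.105). The median Jaccard index was 0.582 between libraries of the same cell type and state and 0.583 between libraries of the same cell type in different states. It was 0.574 between TCRαβ+ and TCRγδ+ IELs, 0.558 between CD4 and CD8 T cells and 0.443 between IELs and peripheral T cells.

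Genes that mark the sorted cell types served as a check of the labels. Of their regions, 4 of 30 differed between the IEL types and 15 of 28 between CD4 and CD8 T cells by limma. The region at one end of Trdc, the constant segment of the TCR delta chain (14:54146291-54147473), had a peak in 22 of 22 TCRγδ+ IEL libraries and 0 of 23 TCRαβ+ IEL libraries (limma, adjusted p = 3.73e-22). It was also found in 5 of 24 CD4 and 7 of 22 CD8 libraries. A region 3.374 kb outside Cd8a, which encodes the CD8 alpha chain (6:71369096-71370053), was present in 22 of 23 TCRαβ+ IEL, 21 of 22 TCRγδ+ IEL, 19 of 22 CD8 and 0 of 24 CD4 libraries (CD4 against CD8, adjusted p = 2.93e-15). A region inside Cd8b1, the CD8 beta chain gene (6:71333623-71334304), was found in 13 of 22 CD8 libraries and 0 libraries of the other cell types (CD4 against CD8, adjusted p = 2.38e-07). A region inside Zbtb7b, which encodes the CD4 lineage factor ThPOK (3:89381973-89382566), was found in 12 of 24 CD4 libraries and 0 of 22 CD8 libraries (adjusted p = 3.47e-05). Other regions were less specific. The region at an end of Zbtb7b (3:89392857-89395283) was present in 20 of 23 TCRαβ+ IEL, 21 of 22 TCRγδ+ IEL, 14 of 24 CD4 and 2 of 22 CD8 libraries, and that at an end of Cd8b1 (6:71322123-71323364) in 19 of 24 CD4 and 20 of 22 CD8 libraries. At an end of Trac, the constant segment of the TCR alpha chain (14:54224020-54226336), a peak was found in 17 of 23 TCRαβ+ and 16 of 22 TCRγδ+ IEL libraries (adjusted p = 0.967) and 0 peripheral libraries, and 0 of 4 tested regions of Trac differed between the IEL types. The only region of Cd4 (6:124884836-124886571) was present in 22 of 24 CD4 and 21 of 22 CD8 libraries, too many for a test between them. Inside Itgae, the gene of the CD103 integrin that binds epithelial cadherin, a region at 11:73100333-73100810 was present in 8 of 23 TCRαβ+ and 6 of 22 TCRγδ+ IEL libraries and 0 peripheral libraries (IEL against peripheral, adjusted p = 1.08e-05).

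**Figure D2:**
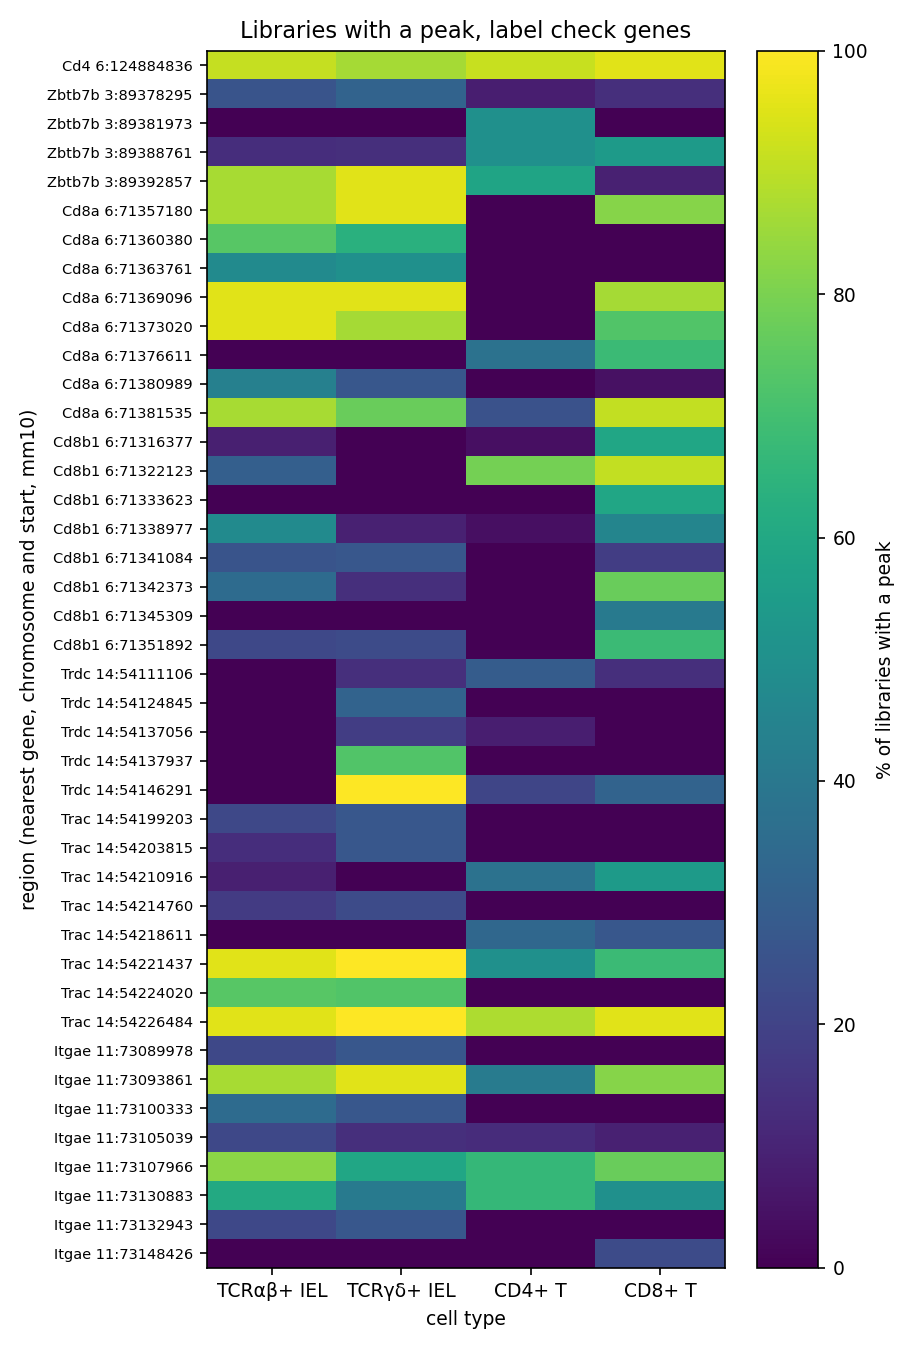
Percentage of libraries of each cell type (columns) with a peak in each region (rows) nearest to the genes that check the labels. The Trdc region starting at 54146291 on chromosome 14 is present in 22 of 22 TCRγδ+ IEL libraries and 0 of 23 TCRαβ+ IEL libraries, and the Cd8a region starting at 71369096 on chromosome 6 in 0 of 24 CD4 libraries.

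Residence in the gut epithelium went with the largest difference in accessible regions. Of 53263 regions tested, 37317 (70.1%) differed between IELs and peripheral T cells, 20027 more often present in IELs and 17290 more often present in peripheral T cells (limma with colonization state and log10 peak number, adjusted p under 0.05). Regions inside Inpp4a (1:37326437-37328279), Myl1 (1:66931521-66932598), Cnih3 (1:181456200-181457711) and Tdp1 (12:99942187-99944128) and a region 244.74 kb from Prep (10:44821236-44822476) had a peak in 45 of 45 IEL libraries and 0 of 46 peripheral libraries (difference in share 1 ± 0.02, SE, adjusted p = 1.16e-62). Regions inside Ptgfrn (3:101065728-101066721) and Itpr1 (6:108524014-108524806), at an end of Dph5 (3:115933238-115934170), 86.338 kb from Oxsm (14:16151713-16152314) and 14.852 kb from Ibtk (9:85671256-85672507) had a peak in 0 of 45 IEL and 45 of 46 peripheral libraries. Of the regions higher in IELs 19.3% lay at a gene end, 49.1% inside a gene and 31.7% between genes, against 8.16%, 51.2% and 40.6% of those higher in peripheral T cells. Among the tested regions not called the shares were 24.6%, 41.5% and 33.9%. Both called sets thus lay at gene ends less often than the regions not called. With Fisher's exact test and no term for peak number 31801 regions were called for IELs against peripheral T cells.

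By gene group, the naive list leaned to peripheral T cells and the cytotoxic effector list to IELs, though neither call held with an estimated correlation. The naive and recirculating T cell list fell in IELs, with 38 of its 227 regions higher in IELs, 157 lower and 32 not called (38 and 158 adjusted over the list alone, camera adjusted p = 2.55e-10). With an estimated correlation its adjusted p was 0.0584. Regions were more often open in peripheral cells at Foxp1 (41 of 59 regions lower in IELs, 11 higher), Bach2 (29 of 38 lower, 5 higher), Lef1 (16 of 20 lower, 2 higher) and S1pr1 (11 of 16 lower, 4 higher). Foxp1, Bach2 and Lef1 encode transcription factors of quiescent T cells, and S1pr1 the receptor through which T cells leave lymphoid organs. At Foxp1, the region 6:99309078-99310159 was present in 2 of 45 IEL and 40 of 46 peripheral libraries (difference -0.83 ± 0.05, SE, adjusted p = 4.61e-27).

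The cytotoxic effector list rose in IELs, with 71 of 125 regions higher, 25 lower and 29 not called (the same 71 and 25 counts adjusted over the list alone, camera adjusted p = 0.00375, and adjusted p = 0.492 with an estimated correlation). Prdm1, which encodes the effector regulator Blimp-1, had 9 of 17 regions higher in IELs and 3 lower, and Ifng, the interferon gamma gene, 8 of 16 higher and 5 lower. A region 9.844 kb from Xcl1, a chemokine gene (1:164945366-164946227), was present in 44 of 45 IEL and 0 of 46 peripheral libraries (difference 0.98 ± 0.03, SE, adjusted p = 3.68e-51). The intraepithelial residency and gut homing list also rose, with 58 of 111 regions higher and 27 lower (58 and 27 adjusted over the list alone, camera adjusted p = 0.0230, and adjusted p = 0.626 with an estimated correlation). Gpr55 had 11 of 13 regions higher and 1 lower, and Itga1, which encodes a collagen-binding integrin of resident T cells, 9 of 12 higher and 2 lower. Other members went the other way, such as Cd69 with 3 of 11 regions higher and 6 lower, and Itga4, the alpha-4 integrin gene, with 2 of 11 higher and 5 lower.

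The NK receptor and adaptor list rose with 38 of 61 regions higher in IELs and 13 lower (38 and 13 adjusted over the list alone, camera adjusted p = 0.0272, and adjusted p = 0.708 with an estimated correlation). Klrg1 had 7 of 8 regions higher and 1 lower, and a region 2.129 kb from Tyrobp, the DAP12 adaptor gene (7:30410821-30411653), was present in 31 of 45 IEL and 0 of 46 peripheral libraries (adjusted p = 3.73e-18). The antimicrobial and tissue repair list rose with 12 of 18 regions higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 0.0116, and adjusted p = 0.492 with an estimated correlation). Its members included the cytokine genes Il17a (38 of 45 IEL and 0 of 46 peripheral libraries at 1:20743525-20744454, adjusted p = 1.19e-28) and Il17f (39 of 45 and 0 of 46 at 1:20766438-20767093, adjusted p = 3.55e-31). It also held Il22 (20 of 45 and 0 of 46 at 10:118195081-118195570, adjusted p = 8.16e-09). None of the 5 list calls in this comparison held with an estimated correlation.

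The other 16 lists passed no camera test, although their regions changed in both directions. The gamma-delta and innate-like list had 38 of 72 regions higher in IELs and 16 lower (camera adjusted p = 0.152), among them Zbtb16, the gene of the innate-like T cell factor PLZF, with 14 of 16 higher and 1 lower. The helper lineage list had 37 of 110 higher and 47 lower (adjusted p = 0.657), with 20 of 29 regions of Ikzf2, the Helios gene, higher and 4 lower, and 7 of 9 regions of Cd40lg, the CD40 ligand gene, lower. The CD8 lineage list had 38 of 86 higher and 29 lower (adjusted p = 0.649), with Runx3 at 14 of 24 higher and 6 lower. In the T cell receptor signalling list 98 of 267 regions were higher and 100 lower (adjusted p = 0.657). The cytokine receptor and JAK-STAT list had 65 of 174 higher and 67 lower (adjusted p = 0.834). There Il6ra, the IL-6 receptor gene, had 9 of 9 regions lower in IELs. The interferon response list had 19 of 46 higher and 11 lower (adjusted p = 0.515). The innate sensing and NF-kB list had 52 of 121 higher and 35 lower (adjusted p = 0.657), and the TGF-beta signalling list 40 of 129 higher and 60 lower (adjusted p = 0.223). Within these, Irf1 had 9 of 12 regions higher and 1 lower, Nod2, which senses bacterial cell walls, 7 of 10 higher and 0 lower, and Tgfbr3 4 of 27 higher and 18 lower.

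Among metabolic lists, glycolysis had 26 of 71 regions higher in IELs and 16 lower (camera adjusted p = 0.836) and fatty acid and cholesterol metabolism 26 of 77 higher and 24 lower (adjusted p = 0.882), with Pfkp at 7 of 10 higher and 1 lower. The label check genes had 22 of 42 regions higher and 11 lower (adjusted p = 0.395), and housekeeping genes 15 of 37 higher and 7 lower (adjusted p = 0.657). Markers of other cell types were measured beside these lists. B cell markers had 7 of 22 regions higher and 11 lower (adjusted p = 0.657), myeloid markers 13 of 38 higher and 14 lower (adjusted p = 0.882), and innate lymphoid and NK markers 41 of 69 higher and 15 lower (adjusted p = 0.158). Intestinal epithelial markers had 13 of 27 regions higher and 8 lower (adjusted p = 0.836), and a region 32.2 kb from Epcam, an epithelial adhesion gene (17:87602981-87603789), was present in 40 of 45 IEL and 0 of 46 peripheral libraries (adjusted p = 4.52e-33). In the T cell receptor signalling, cytokine receptor and myeloid lists the median difference was above 0 while the mean and the camera direction were below it.

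**Figure D3:**
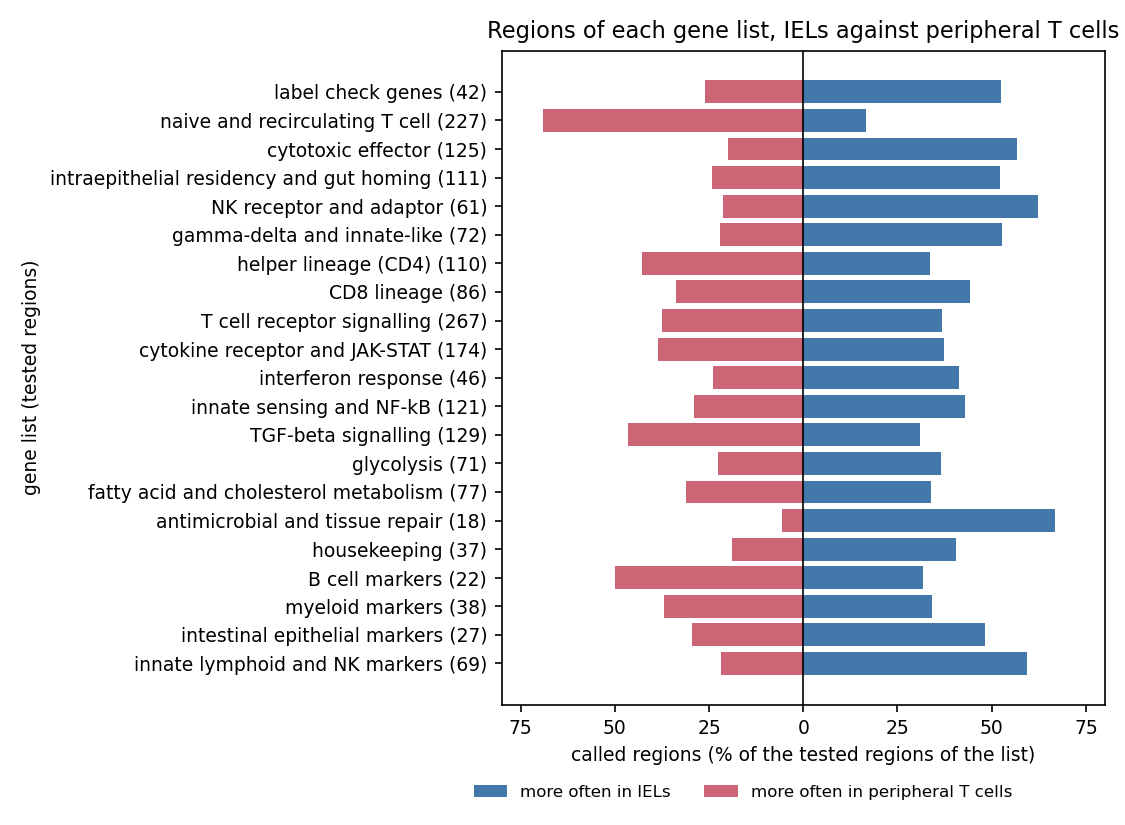
Regions called more often present in IELs (right) or in peripheral T cells (left), as a percentage of the tested regions of each gene list, with the number tested in brackets. The naive and recirculating list leans to peripheral T cells (157 of 227 regions) and the antimicrobial and tissue repair list to IELs (12 of 18).

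Between the IEL types far fewer regions differed. Of 37982 regions tested, 791 (2.08%) passed, 602 more often present in TCRαβ+ IELs and 189 in TCRγδ+ IELs. Apart from the Trdc regions, TCRγδ+ IELs had peaks 596.924 kb from Sall1 (8:89641086-89641776, 16 of 22 against 1 of 23 libraries, adjusted p = 8.79e-11) and inside Ncam2 (16:81437412-81437936, 15 of 22 against 1 of 23, adjusted p = 2.52e-09). TCRαβ+ IELs had peaks inside Plcb4 (2:135890882-135891685, 22 of 23 against 2 of 22, difference 0.85 ± 0.09, SE, adjusted p = 1.57e-15). Others lay inside Ntrk3 (7:78451418-78452442, 19 of 23 against 0 of 22, adjusted p = 3.29e-14) and Gpr183, an oxysterol receptor gene (14:121954152-121956021, 18 of 23 against 0 of 22, adjusted p = 3.53e-12).

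The T cell receptor signalling list was higher in TCRαβ+ IELs, with 13 of 200 regions higher and 0 lower (16 and 1 adjusted over the list alone, camera adjusted p = 0.0398, and adjusted p = 0.452 with an estimated correlation). The called regions lay near Cd6 (6 of 10) and Cd5 (5 of 9), whose products restrain TCR signals, and near Prkcq (1 of 17) and Itk (1 of 10). Most of the 13 thus came from Cd6 and Cd5 and not from across the list. Cd28, the costimulatory receptor gene, had 5 of 6 regions higher, including 1:60745673-60746690 in 20 of 23 TCRαβ+ and 4 of 22 TCRγδ+ libraries (adjusted p = 3.51e-09). The naive list that holds it had 5 of 109 regions higher and 2 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.0834). The gamma-delta and innate-like list was lower in TCRαβ+ IELs, with 2 of 57 regions higher and 5 lower (2 and 12 adjusted over the list alone, camera adjusted p = 0.00110, and adjusted p = 0.132 with an estimated correlation). The 5 were 3 of Trdc and 2 of Trdv4, segments of the TCR delta locus, and the 2 lay near Maf and Gata3. The called lower regions thus came from a single locus, where an absent peak cannot tell closed chromatin from missing DNA. In the helper lineage list 5 of 72 regions were higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 0.677), near Icos, Ctla4, Gata3 and Cd40lg. Icos and Ctla4 lie close to Cd28 on chromosome 1, so their regions are not separate support. The residency list had 0 of 90 regions called by limma and 0 adjusted over the list alone. Neither list call held with an estimated correlation. For TCRαβ+ against TCRγδ+ IELs, Fisher's exact test gave 101 regions, the fit without the peak number term 196 higher in TCRαβ+ and 19 in TCRγδ+ IELs, and the longest 8000 peaks of each list 10 and 18. With the library number as a block the count of 791 regions also fell, and 20 of 35 named regions lost the threshold. When at least 50% of a region had to be covered the split was 211 and 167, and without the libraries under 10000 peaks it was 634 and 408. In the helper lineage, CD8 lineage, housekeeping, residency and myeloid lists the median and the mean difference had opposite signs, and the camera direction followed the mean.

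CD4 and CD8 T cells differed at 7202 of 36682 regions (19.6%), with 2397 more often present in CD4 and 4805 in CD8 T cells. CD4 T cells had peaks inside Polr1a (6:71920483-71921380) and Ibtk (9:85710021-85711130) and 23.764 kb from Slc14a2 (18:78620714-78621419) in 24 of 24 libraries against 0 of 22 (difference 1 ± 0.06, SE, adjusted p = 1.31e-22). CD8 T cells had a peak 12.877 kb from Neto2 (8:85623017-85623841) in 22 of 22 against 0 of 24 libraries (adjusted p = 1.31e-22). They had another 0.852 kb from Adgrg1, a receptor gene of cytotoxic lymphocytes (8:94973042-94973904), in 20 of 22 against 0 of 24 (difference -0.91 ± 0.07, SE, CD4 minus CD8, adjusted p = 3.07e-16).

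The lists that passed all leaned to CD8 T cells. The CD8 lineage list had 24 of 52 regions higher in CD8 and 4 in CD4 T cells (25 and 4 adjusted over the list alone, camera adjusted p = 5.57e-06, and adjusted p = 0.0213 with an estimated correlation). In CD8 T cells 5 of 5 regions of Cd8a and 6 of 8 of Cd8b1 were higher. Tox, a factor of T cell development, went both ways, with 3 of 12 regions higher in CD4 and 2 in CD8 T cells. The label check genes had 13 of 28 regions higher in CD8 and 2 in CD4 T cells (13 and 2 adjusted over the list alone, camera adjusted p = 2.69e-05, and adjusted p = 0.0213 with an estimated correlation). The NK receptor and adaptor list had 11 of 26 higher in CD8 and 0 in CD4 T cells (12 and 0 adjusted over the list alone, camera adjusted p = 0.00189, and adjusted p = 0.0285 with an estimated correlation). Il2rb, the IL-2 receptor beta gene, had 3 of 4 regions higher in CD8 T cells. The cytotoxic effector list had 26 of 70 higher in CD8 and 6 in CD4 T cells (30 and 6 adjusted over the list alone, camera adjusted p = 0.00132, and adjusted p = 0.0806 with an estimated correlation). Ifng had 9 of 14 regions higher in CD8 and 1 in CD4 T cells, and the region at an end of Gzmb, the granzyme B gene (14:56261635-56262896), was present in 17 of 22 CD8 and 0 of 24 CD4 libraries (adjusted p = 1.59e-12).

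Markers of B cells moved with the same side. Of 14 B cell marker regions, 6 were higher in CD8 and 1 in CD4 T cells (6 and 1 adjusted over the list alone, camera adjusted p = 0.0296, and adjusted p = 0.148 with an estimated correlation). The regions were near Pax5 (3 of 3), Cd19, Cd22 and Bank1, and a region inside Pax5, the B lineage factor gene (4:44674795-44675415), was present in 16 of 22 CD8 and 0 of 24 CD4 libraries (adjusted p = 6.19e-11). Kit, in the innate lymphoid list, had 4 of 4 regions higher in CD8 T cells. The calls of the CD8 lineage, label check and NK lists held with an estimated correlation, and those of the cytotoxic and B cell lists did not. The CD8 lineage and label check lists share the regions of Cd8a and Cd8b1, which lie close together on chromosome 6. Both genes encode the marker that defines CD8 T cells, so the calls of these lists are not separate support. For the naive, helper lineage, interferon, TGF-beta, glycolysis and myeloid lists the median and mean were below 0 while the camera direction was up, because camera ranks a list against all other regions. Without the libraries under 10000 peaks the split for CD4 against CD8 T cells was 4004 and 4061 regions, and Fisher's exact test gave 3650 regions.

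Whether microbes alter accessibility was asked within each cell type. In TCRαβ+ IELs, germ-free and conventionally raised mice differed at 52 of 22848 regions, 14 more often present in germ-free and 38 in conventionally raised mice. Germ-free libraries more often had a peak inside Lat2, which encodes a signalling adaptor (5:134613248-134614556, 8 of 8 against 1 of 8, difference 0.87 ± 0.18, SE, adjusted p = 0.00466). The same held at an end of Gdf11 (10:128890515-128892794) and inside Myo1e (9:70246283-70246910), both in 8 of 8 against 1 of 8 (adjusted p = 0.00903). Another lay inside Cerk, the ceramide kinase gene (15:86164672-86165580, 7 of 8 against 0 of 8, adjusted p = 0.0159). Conventionally raised libraries more often had a peak inside Oxct1, a ketone body enzyme gene (15:4124487-4125248, 7 of 8 against 0 of 8, difference -0.89 ± 0.18, SE, germ-free minus conventionally raised, adjusted p = 0.00466) and 87.335 kb from Cep44 (8:56443536-56444181, 7 of 8 against 0 of 8, adjusted p = 0.00466). Further regions lay inside Ryr2 (13:11957703-11958730), Ext1 (15:53266008-53268060) and Decr1 (4:15928974-15929781), each in 6 of 8 against 0 of 8 libraries (adjusted p = 0.00466). Mef2c, a transcription factor gene, held a region higher in germ-free (13:83597350-83598118, 7 of 8 against 0 of 8, adjusted p = 0.0159) and a pair higher in conventionally raised mice (13:83565751-83566690 and 13:83608816-83609875, 6 of 8 against 0 of 8, adjusted p = 0.00466). In this comparison limma assigned every region the same variance. No gene list passed (lowest camera adjusted p = 0.0585, naive and recirculating, lower in germ-free mice). Of the listed regions 19 passed adjusted over the list alone, against 2 over all regions, both of the NK receptor and adaptor list.

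For germ-free against conventionally raised TCRαβ+ IELs the 52 regions fell to 0 without the peak number term and to 0 with Fisher's exact test, which had 944 regions at an unadjusted p under 0.05. They fell to 0 with the longest 50% or 8000 peaks of each list and to 8 when at least 50% of a region had to be covered. The count was 277, 92, 31, 30, 18 and 30 without germ-free library 2, 4, 5, 6, 7 or 8, and 33, 295 and 189 without conventionally raised library 4, 6 or 7, where library 6 holds 8015 peaks. It was 306 with a term for library numbers 1 to 4 against 5 to 8, chosen after the data were seen.

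Germ-free and conventionalized TCRαβ+ IELs differed at 0 of 25530 regions by limma, with 1184 at an unadjusted p under 0.05, and at 0 by Fisher's exact test. Among list genes with the smallest p-values, a region inside Pfkp, a glycolytic enzyme gene (13:6636267-6637289), was present in 6 of 8 germ-free and 0 of 7 conventionalized libraries. So was a region 1.162 kb from Cd27, a costimulatory receptor gene (6:125238298-125238905). Both had an adjusted p of 0.874. Conventionally raised and conventionalized TCRαβ+ IELs differed at 1 of 15470 regions, on chromosome Y 524.703 kb from the predicted gene Gm20812 (Y:11857862-11858481). It was present in 8 of 8 conventionally raised and 0 of 7 conventionalized libraries (difference 1 ± 0.20, SE, adjusted p = 0.00595). By Fisher's exact test and without the peak number term 0 regions passed, and the limma count was 2 without conventionally raised library 6 and 0 without conventionalized library 1 or 2. The naive and recirculating list was higher in conventionally raised mice, with 0 of 52 regions called and 0 adjusted over the list alone (camera adjusted p = 0.0349, and adjusted p = 0.953 with an estimated correlation).

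In TCRγδ+ IELs, germ-free and conventionally raised mice differed at 29 of 24966 regions, 28 more often present in germ-free mice and 1 in conventionally raised mice. The regions higher in germ-free mice included those inside Ppm1l, a phosphatase gene (3:69468497-69469172, 7 of 8 against 0 of 8 libraries, difference 0.81 ± 0.18, SE, adjusted p = 0.0213) and at an end of Golm1 (13:59674713-59676118, 8 of 8 against 1 of 8, adjusted p = 0.0213). Others lay inside Crppa (12:36439380-36439880), Nrcam (12:44344037-44344615) and Vrk1 (12:106029560-106030777), each in 7 of 8 against 0 of 8 (adjusted p = 0.0213). The region higher in conventionally raised mice lay 19.449 kb from Sec11c (18:65837109-65837582, 5 of 8 against 0 of 8, adjusted p = 0.0223). No gene list passed (lowest camera adjusted p = 0.214). The count was 0 with Fisher's exact test (2280 regions at an unadjusted p under 0.05), without the peak number term and with at least 50% of the region covered. It was 0 as well with the library number as a block. It was 377 without germ-free library 3, 1 without conventionally raised library 7 and 0 without conventionally raised library 8.

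Conventionalized TCRγδ+ IELs differed from germ-free ones at 0 of 24903 regions by limma, with 726 at an unadjusted p under 0.05, and from conventionally raised ones at 0 of 14786, with 720 at that level. Fisher's exact test gave 0 in both comparisons. The region at an end of Ikzf2 (1:69686808-69688384) was present in 3 of 8 conventionally raised and 6 of 6 conventionalized libraries (adjusted p = 0.925).

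In CD4 T cells, conventionally raised and conventionalized mice differed at 9 of 21477 regions, all more often present in conventionalized mice. They lay 133.202 kb from Erbb4 (1:69241778-69242270, 7 of 8 against 1 of 8 libraries), 27.882 kb from Ctsc, the cathepsin C gene (7:88343743-88344304, 8 of 8 against 2 of 8), and inside Magi2 (5:20470404-20470841, 7 of 8 against 1 of 8). Others lay at an end of Snap23 (2:120567226-120568223) and inside Cdk6, a cell cycle kinase gene (5:3420432-3421295), each in 8 of 8 against 2 of 8, and the adjusted p was 0.0358 for all 5. The difference at Cdk6 was 0.71 ± 0.16 (SE). The remaining regions lay near D16Ertd472e, Stab2 and Elovl4 (adjusted p = 0.0358) and B3glct (adjusted p = 0.0475). The count was 0 with Fisher's exact test (102 regions at an unadjusted p under 0.05), without the peak number term and without libraries under 10000 peaks. It stayed 0 with the library number as a block and with a term for library numbers 1 to 4 against 5 to 8. It was also 0 without conventionally raised library 1, 2, 5, 6 or 8 or conventionalized library 3, 4, 6 or 8, 1 without conventionally raised library 3 or conventionalized library 5, and 3 without conventionally raised library 4.

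Germ-free CD4 T cells differed from conventionally raised ones at 0 of 19158 regions by limma, with 1005 at an unadjusted p under 0.05, and from conventionalized ones at 0 of 21504, with 1331 at that level. Fisher's exact test gave 0 in both. A region inside Ppargc1a, a regulator of mitochondrial genes (5:51551914-51553268), was present in 7 of 8 germ-free and 1 of 8 conventionally raised libraries (adjusted p = 0.482). Regions near Ctla4 (1:60860484-60861034) and inside Cd247, the CD3 zeta chain gene (1:165810536-165811060), were present in 1 of 8 germ-free and 5 of 8 conventionalized libraries (adjusted p = 0.469). A region 23.616 kb from Nos2 (11:78896704-78897171) was present in 0 of 8 and 4 of 8 (adjusted p = 0.505). CD8 T cells had 0 called regions by limma and by Fisher's exact test in all 3 comparisons, and 1 between conventionally raised and conventionalized mice with a term for library numbers 1 to 4 against 5 to 8. By limma, 1136 of 18556 regions were at an unadjusted p under 0.05 between germ-free and conventionally raised mice, 407 of 18281 between germ-free and conventionalized mice, and 2287 of 18770 between conventionally raised and conventionalized mice. No gene list passed in the peripheral T cell comparisons between states. In simulated data of the same libraries, 0 of 100 regions with a large shift in the odds of a peak were recovered in each of these 6 comparisons, so a count of 0 does not show that the states were alike.

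The difference between germ-free and conventionally raised mice was itself compared between IELs and peripheral T cells. Of 50201 regions, 7580 passed, 6989 where germ-free minus conventionally raised was larger in IELs and 591 where it was smaller. A region inside Cap1, an actin regulator gene (4:122870690-122871260), was present in 13 of 16 germ-free and 0 of 16 conventionally raised IEL libraries and in 0 peripheral libraries of these states, and its difference exceeded that of peripheral T cells by 0.82 ± 0.10 (SE, adjusted p = 8.64e-07). The regions inside Nrcam (12:44344037-44344615, 13 of 16 against 0 of 16, adjusted p = 8.64e-07), Cerk (15:86164672-86165580, 14 of 16 against 1 of 16, adjusted p = 1.62e-06) and Enox1 (14:77458187-77458646, 14 of 16 against 1 of 16, adjusted p = 3.83e-06) behaved alike. In 10 of the 10 named regions of this direction 0 peripheral libraries had a peak, so the peripheral difference was fixed at the floor there. How many of the 6989 were such regions was not counted. The difference was smaller in IELs inside Oxct1 (15:4124487-4125248, 0 of 16 germ-free and 7 of 16 conventionally raised IEL libraries, -0.57 ± 0.10, SE, adjusted p = 0.000177) and near Cep44 (8:56443536-56444181, 0 of 16 and 7 of 16, adjusted p = 0.000208). In 5 of the 10 named regions of this direction the IELs did not differ and the difference lay in peripheral T cells. Among them were a region 1.648 kb from B3gnt2 (11:22832480-22833091, 0 IEL libraries, 9 of 16 germ-free and 1 of 15 conventionally raised peripheral libraries, adjusted p = 0.000467) and one at an end of Slc6a6 (6:91682910-91685470, 16 of 16 IEL libraries in both states, 16 of 16 and 6 of 15 peripheral libraries, adjusted p = 0.000921).

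Of the gene lists only the naive and recirculating list passed in this comparison, with 11 of 214 regions larger in IELs and 9 smaller (11 and 4 adjusted over the list alone, camera direction down, adjusted p = 0.00124, and adjusted p = 0.943 with an estimated correlation). The NK receptor and adaptor list had 19 of 61 regions larger and 0 smaller (24 and 0 adjusted over the list alone, camera adjusted p = 0.0542). When each cell type was given its own slope on peak number, a fit chosen after the count was seen, 430 regions passed, 372 larger and 58 smaller in IELs, and 389 of them were among the 7580. With the longest 8000 peaks of each list 89 larger and 39 smaller regions passed. In data simulated from the same libraries with no effect of colonization, a median of 131.5 and a highest count of 226 regions passed in 10 simulations.

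The changes from germ-free to conventionally raised and from germ-free to conventionalized mice were set side by side within each cell type. They share the germ-free libraries, so values are given beside those simulated with no effect. In TCRαβ+ IELs the covariance of the differences over 29728 regions was 0.0265 against 0.0220 simulated, and in TCRγδ+ IELs 0.0239 over 29368 regions against 0.0217 simulated (20 simulations each). In CD4 T cells it was 0.0140 over 26698 regions against 0.0185 simulated and in CD8 T cells 0.00576 over 26611 regions against 0.0122 simulated. The correlation across regions, which are not independent replicates, was 0.616 in TCRαβ+ IELs (0.569 simulated), 0.648 in TCRγδ+ IELs (0.573 simulated), 0.483 in CD4 (0.548 simulated) and 0.174 in CD8 T cells (0.318 simulated). With the germ-free libraries split between the comparisons it was 0.323 in TCRαβ+ IELs (0.173 simulated), 0.333 in TCRγδ+ IELs (0.175 simulated), 0.0571 in CD4 (0.0510 simulated) and -0.148 in CD8 T cells (-0.0802 simulated). Comparisons of germ-free with conventionalized mice called 0 regions by limma in every cell type, so no overlap of called regions could be counted.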

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

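The splits of the libraries, the separate slopes and the squared terms were chosen after the result was seen. Of 24 group and measure combinations examined for a library far from its group, 3 stood out, and chance alone picks about 1 in 20 groups. Conventionally raised TCRαβ+ IEL library 6 lay below its group in log10 peak number (8015 peaks), with a gap to the nearest library of 0.594 of the group's range. The same library had the highest share of peaks at gene ends in its group (66.1%), with a gap of 0.650 of the range. Germ-free CD8 library 2 had the highest share of gene-end peaks in its group (53.1%, 10001 peaks), with a gap of 0.531 of the range.

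The difference between germ-free and conventionally raised mice differed between IELs and peripheral T cells at 7580 regions by a test of the difference itself, and 6989 of them were larger in IELs. Of 100 splits of the libraries 1, the real one, gave as many, and the highest other split gave 394. The splits took libraries as independent, whatever their number, and did not keep the link of state with peak number. Chance is excluded only within these limits. With the library number as a block 20 of 20 named regions still passed. They were chosen for the smallest adjusted p-values in each direction, so that they passed is weak support. Data simulated with no effect at the real peak numbers gave a median of 131.5 and a highest count of 226 regions. A relation of presence to peak number that differs between cell types was examined by giving each cell type its own slope, which left 430 regions, with 65 in the highest other of 100 splits fitted the same way. Such splits break the link of state with peak number, through which unequal slopes would act. They therefore cannot decide whether these slopes are the whole cause, and no data simulated with no effect were fitted this way. Most of the 7580 no longer passed. A relation to peak number that is curved stays open, since squared terms left 364 regions with a curve per cell type and 145 with a curve each for IELs and peripheral T cells, and those counts were not set against splits. The count of 145 lies below the highest count simulated with no effect, which came from the fit with a common slope. A difference in the response of the tissues to microbes, which the design names, may account for part of the 430 and was not tested apart from these.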

How the results depend on the processing

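Omission of single libraries, other peak number slopes and a term for library numbers 1 to 4 against 5 to 8 were chosen after the results were seen, and the other alternatives before. Of 340 alternative values of the main results, 238 stayed on the same side, 101 moved and 1 reversed, and of 1403 values for named regions and lists 1216 stayed, 185 lost the threshold and 2 reversed. The cause was not tested except where the construction shows it, as with fewer or more regions in windows or shortened lists. Depth is unknown, so differences missed for lack of reads cannot be counted, and the groups of 6 to 8 libraries recovered almost none of the simulated shifts. Motif tests, with and without covariates and on distal regions only, were not run, and Fisher's exact test gives no value for the comparison of colonization differences.

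With at least 50% of a region covered there were 378 regions for TCRαβ+ against TCRγδ+ IELs, 8 for germ-free against conventionally raised TCRαβ+ IELs, and 0 for conventionally raised against conventionalized TCRαβ+ IELs. There were 0 for germ-free against conventionally raised TCRγδ+ IELs, 1 for germ-free against conventionalized TCRγδ+ IELs and 0 for conventionally raised against conventionalized CD4 T cells. There the Ctsc region reversed (adjusted p = 0.877 by limma) and so did that of Ptpn13 for the difference in colonization effects (adjusted p = 0.229 by limma). With the longest 50% of each list the counts were 18729 for IELs against peripheral T cells, 230 for the IEL types, 2626 for CD4 against CD8 T cells, 3458 for colonization differences, 1 for germ-free against conventionalized CD8 T cells and 0 for the 4 comparisons between states with calls. Regions in at least 10 libraries gave 5000 for colonization differences. Windows of 500 bp gave 87558, 1273 and 13171 for the cell type comparisons, 15639 for colonization differences, 0 for germ-free against conventionally raised TCRγδ+ IELs and 0 for conventionally raised against conventionalized CD4 T cells. Without the peak number term the counts were 215 for the IEL types, 4431 for CD4 against CD8 T cells, 4127 for colonization differences and 0 for the 4 comparisons between states. Fisher's exact test gave 101 for the IEL types, 3650 for CD4 against CD8 T cells and 0 for the 4 comparisons between states.

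Without libraries under 10000 peaks there were 295 regions for germ-free against conventionally raised TCRαβ+ IELs, 1 for germ-free against conventionalized and 0 for conventionally raised against conventionalized TCRαβ+ IELs, 0 for conventionally raised against conventionalized CD4 T cells and 4799 for colonization differences. The covariance of the changes against germ-free was then 0.0233 in TCRαβ+ IELs (0.0193 simulated with no effect), 0.0233 in TCRγδ+ IELs (0.0203 simulated) and 0.0105 in CD8 T cells (0.0161 simulated). The peak number difference between conventionally raised and conventionalized TCRγδ+ IELs, not past the threshold either way, changed sign (exact permutation, adjusted p = 0.767). The longest 8000 peaks gave 9465 for IELs against peripheral T cells, 28 for TCRαβ+ against TCRγδ+ IELs, 883 for CD4 against CD8 T cells, 128 for colonization differences and 0 for the 4 comparisons between states. For colonization differences, a slope per cell type gave 430, one slope for IELs and one for peripheral T cells 409, squared terms per cell type 364 and squared terms for IELs and peripheral T cells 145. With a term for library numbers 1 to 4 against 5 to 8 there were 306 for germ-free against conventionally raised TCRαβ+ IELs, 0 for conventionally raised against conventionalized CD4 and 1 for such CD8 T cells.

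With an estimated correlation 0 gene lists were called for IELs against peripheral T cells, 0 for the IEL types, 3 for CD4 against CD8 T cells, 0 for conventionally raised against conventionalized TCRαβ+ IELs and 0 for colonization differences. Within 10 kb the counts were 3 for IELs against peripheral T cells, 0 for conventionally raised against conventionalized TCRαβ+ IELs and 2 for colonization differences. Within 100 kb they were 1 for the IEL types, 1 for germ-free against conventionally raised TCRαβ+ IELs and 1 for conventionally raised against conventionalized CD4 T cells.

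Leaving out 1 library at a time gave 18 to 295 regions for germ-free against conventionally raised TCRαβ+ IELs (277, 92, 31, 30, 18 and 30 without germ-free 2, 4, 5, 6, 7 and 8, and 33, 295 and 189 without conventionally raised 4, 6 and 7). The range was 0 to 2 for conventionally raised against conventionalized TCRαβ+ IELs (2 without conventionally raised 6, 0 without conventionalized 1 or 2) and 0 to 377 for germ-free against conventionally raised TCRγδ+ IELs (377 without germ-free 3, 1 and 0 without conventionally raised 7 and 8). For conventionally raised against conventionalized CD4 T cells it was 0 to 10, with 0 without conventionally raised 1, 2, 5, 6 or 8 or conventionalized 3, 4, 6 or 8, 1 without conventionally raised 3 or conventionalized 5, and 3 without conventionally raised 4.

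Libraries share numbers across groups, and the labels do not say what a number marks. Deviations from the group mean correlated above 0.1 in 27 of 130 same-numbered pairs of cell types within a state and in 31 of 86 same-numbered pairs of states within a cell type. Among TCRαβ+ with TCRγδ+ IELs it was 7 of 8 in germ-free, 5 of 8 in conventionally raised and 4 of 6 in conventionalized mice. In 0 pairs of groups did all do so, so by that bound the numbers were not taken as pairing the libraries. That bound cannot exclude a pairing, since many same-numbered IEL libraries did deviate together. Among these same-numbered pairs 37 of 130 and 17 of 86 correlated best with their own number. With the number as a block there were 124 regions for the IEL types, 147 for germ-free against conventionally raised TCRαβ+ IELs, 2 for conventionally raised against conventionalized TCRαβ+ IELs, 0 for germ-free against conventionally raised TCRγδ+ IELs and 0 for conventionally raised against conventionalized CD4 T cells, and the block moved no other count by over 1.5 times. With the block, 20 of 35 named regions of the IEL types, 11 of 11 of that TCRγδ+ IEL comparison and 9 of 9 of that CD4 comparison lost the threshold.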

Other observations

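The splits of the libraries and the tests of peripheral-type regions, of the states with cell types pooled and of the regions on the sex chromosomes were chosen after the results were seen. Genes of other groups also differed between IELs and peripheral T cells. A region of Runx3, which encodes a factor of the CD8 lineage and of tissue residence (4:135167821-135169913), was present in 43 of 45 IEL and 0 of 46 peripheral libraries (limma, adjusted p = 3.42e-44). A region of Tgfbr3, a TGF-beta co-receptor gene (5:107101000-107101592), was present in 0 of 45 and 42 of 46. Between the IEL types, a region near Areg, the amphiregulin gene (5:91139256-91139993), was present in 15 of 23 TCRαβ+ and 3 of 22 TCRγδ+ libraries (adjusted p = 6.26e-05). Between CD4 and CD8 T cells, a region near Bcl6, a regulator of follicular helper cells (16:23997116-23997657), was present in 16 of 24 CD4 and 2 of 22 CD8 libraries (adjusted p = 4.13e-06). In its median and mean difference the helper lineage list, which holds Bcl6, leaned to CD8 T cells. So did the called regions of this comparison as a whole (4805 against 2397). Set against all other regions, the camera direction of the list was to CD4 T cells, though it did not pass.

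Peak number followed the library number in germ-free and conventionalized mice. In 7 of 12 groups every library numbered 5 to 8 held more peaks than every library numbered 1 to 4. In germ-free mice libraries 5 to 8 held 44772 to 48745 peaks in TCRαβ+ IELs, 41284 to 49510 in TCRγδ+ IELs and 31723 to 42933 in CD4 T cells. Libraries 1 to 4 held 12469 to 24560, 10129 to 28472 and 14968 to 24946 in the same order. In conventionalized mice libraries 5 to 8 held 25547 to 44978, 30766 to 40575, 32458 to 43708 and 34915 to 43977 peaks in TCRαβ+ IELs, TCRγδ+ IELs, CD4 and CD8 T cells. Libraries 1 to 4 held 7571 to 22743, 8568 to 21211, 7375 to 28319 and 12686 to 28411. The ranges overlapped in germ-free CD8 T cells (27671 to 40192 against 10001 to 30860) and in the 4 conventionally raised groups, such as TCRαβ+ IELs (8015 to 33513 against 20882 to 27381). The labels do not say whether the numbers mark animals, days or batches.

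Of the 38 regions more often present in conventionally raised than in germ-free TCRαβ+ IELs, 35 (92.1%) were of a kind more often present in peripheral T cells than in TCRγδ+ IELs, against 19.0% of the regions tested. Of the 14 higher in germ-free mice 13 (92.9%) were of the opposite kind, against 42.3% of the regions tested. For the 38, the mean share present was 6.58% ± 7.31 (SD, n = 8) in germ-free, 73.0% ± 39.3 (SD, n = 8) in conventionally raised and 22.6% ± 28.3 (SD, n = 7) in conventionalized TCRαβ+ IELs, where it was 12.7% ± 12.2 (SD, n = 6) without library 4. It was 83.3% in CD4 and 78.2% in CD8 T cells. The germ-free and conventionally raised values follow from how the 38 were chosen, so they are no separate support. The conventionalized libraries took no part in that choice. Longer lists held more of the 38 in CD4 (Pearson's r = 0.931, Spearman's rho = 0.909, n = 24) and CD8 T cells (0.955 and 0.780, n = 22), which took no part in choosing them (each permutation p = 1e-04, the smallest these permutations can give). Since germ-free lists were longer on average, this goes against a difference in peak number. It stays open, because in TCRγδ+ IELs r was 0.268 and rho 0.380 (n = 22, permutation p = 0.226 and 0.0817) and because 0 regions passed without the peak number term. Without the 2 libraries farthest from the median, r was 0.912, 0.861 and 0.179 in these cell types. Peripheral T cells in the sorted fraction could also give the pattern and cannot be told apart. The other 14241 regions of this kind had a share of 26.0% ± 16.5 (SD, n = 8) in germ-free and 21.6% ± 11.8 (SD, n = 8) in conventionally raised libraries (exact permutation p = 0.540). Adjusted for peak number the conventionally raised share was 3.74 points higher (exact permutation p = 0.109, Benjamini-Hochberg p = 0.654), and in TCRγδ+ IELs, where the gate would remove such cells, it differed by -0.091 points. A change of the IELs with colonization, which the design names, was not tested apart from these.

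With the cell types pooled, the 3 pairs of states gave 4, 0 and 5 called regions, and the regions of Mid1 and Gm52481 lay on the sex chromosomes. A region inside Mid1, a gene that spans the pseudoautosomal boundary (X:169972778-169973603), was present in 0 of 32 germ-free, 14 of 31 conventionally raised and 0 of 28 conventionalized libraries. Regions at an end of Gm52481 were present in 19, 0 and 11 (Y:90740866-90742860) and in 6, 0 and 14 (Y:90743058-90744912) of them. By library number, 0, 6 and 0 of 8 numbers had the Mid1 peak in these states, and 5, 0 and 4 and then 4, 0 and 6 of 8 those of Gm52481. The regions were chosen by a limma fit with a peak number term that takes same-numbered libraries as independent, so its p-values are not given, and peak number was not tested apart. Presence at the Gm52481 regions was shared by same-numbered libraries of a state more than with shuffled numbers (permutation p = 1e-05, the smallest that these permutations can give, and 0.00187), and at Mid1 the permutation p was 0.0982. The other called regions, on autosomes, showed such sharing at Inpp4b (permutation p = 3e-05), Satb1 (0.00285) and Fli1 (0.00992), and Egf had 0.0733. A variant between animals may account for the sex chromosome regions, but since sharing by number was not particular to them it cannot be told apart from whatever else the numbers mark, or from the state. Sharing by number within a state cannot test a variant that differs between the mice of different states.

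Of 100 splits of the libraries, 1 gave as many regions as the real split for IELs against peripheral T cells (37317 regions, highest other 5) and for TCRαβ+ against TCRγδ+ IELs (791, highest other 153). So it did for CD4 against CD8 T cells (7202, highest other 79). Chance is excluded for IELs against peripheral T cells and for CD4 against CD8 T cells. With the library number as a block 92 of 92 and 83 of 83 named regions of these stayed. The named regions were chosen for large differences or small p-values, so that they stayed is weak support. For the IEL types 20 of 35 lost the threshold with the block, so splits of independent libraries cannot exclude chance there. For germ-free against conventionally raised TCRγδ+ IELs 1 split gave as many (29, highest other 9), but that count was 0 without conventionally raised library 8. The splits took libraries as independent, whatever their number. For germ-free against conventionally raised TCRαβ+ IELs 2 of 100 splits gave as many (52 regions, highest other 148). For conventionally raised against conventionalized CD4 T cells 2 of 100 did so too (9 regions, highest other 1275). Adjusted over the 16 comparisons by Benjamini-Hochberg, the share of splits was 0.0457 for both. Both counts fell to 0 with Fisher's exact test and without the peak number term, so chance is not firmly excluded for the 52. With the block 9 of 9 named CD4 regions lost the threshold, so the splits cannot exclude chance there. For conventionally raised against conventionalized TCRαβ+ IELs (1 region, 3 of 100, highest other 27) the adjusted share was 0.06, so chance is not excluded there once adjusted. In these 3 the highest other split exceeded the real count, and the counts of 1 and 9 fell to 0 without single libraries. Such splits may reflect a structure of the samples or the correlation of regions within a library, which were not tested.

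For the comparisons with 0 called regions by limma the number of regions at an unadjusted p under 0.05 was used, and chance is not excluded in any. For germ-free against conventionalized mice it was 1184 in TCRαβ+ IELs (36 of 100 splits as large, highest other 10081), 726 in TCRγδ+ IELs (52 of 100, highest other 6055), 1331 in CD4 (30 of 100, highest other 4065) and 407 in CD8 T cells (86 of 100, highest other 3098). For germ-free against conventionally raised mice it was 1005 in CD4 (26 of 100, highest other 6018) and 1136 in CD8 T cells (29 of 100, highest other 4742). For conventionally raised against conventionalized mice it was 720 in TCRγδ+ IELs (31 of 100, highest other 2770) and 2287 in CD8 T cells (11 of 100, highest other 5741). The highest other split exceeded the real number in each, and Fisher's exact test called 0 regions in each.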
